A study of Mus musculus with 18 samples.

How the data were processed

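The deposited table held raw read counts per Ensembl gene for 18 RNA-seq libraries of BV-2 cells, 3 for each of 6 groups. Per the labels' protocols, the vehicle in all cultures was α-cyclodextrin at 0.5 mM with ethanol at 0.01%, LPS came from E. coli, and poly(A) libraries were made with a stranded kit from 1000 ng of RNA with 12 PCR cycles. Per the labels, the RNA of each genotype came from 3 independent batches of cells. The labels do not say that a replicate number marks a batch. The tools named in the submitters' processing notes are cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a and HTSeq 0.6.1p1, with the genome build mm10. Their settings, the strand option and the annotation release are not stated there, so overlapping, antisense and near-identical genes, such as members of the class I family, are uncertain. The labels' protocols mention no molecular identifiers, so reads are not independent molecules. Of the 28769 gene identifiers, 28720 were found in GENCODE M21 (mm10), which gave symbols and coordinates, and the other 49 were kept under their identifier.

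All statistics were computed from these counts with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr with the 6 groups, which left 15131 genes, and libraries were scaled by TMM factors. One model with a coefficient per group was fitted to all 18 libraries (12 residual degrees of freedom) with glmQLFit and robust estimation. The comparisons were each mutant against WT and against the other mutant without LPS, LPS against untreated cells in each genotype, and the difference of each mutant's LPS response from that of WT. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and the SE of a log2 fold change was its size divided by the square root of F. CPM were computed from the deposited counts with the TMM-scaled library sizes. Where a group had no counts, a fold was computed against 3 counts over the group and given as a lower bound, and with 1 to 3 counts the ratio was given with its 95% counting interval. Leaving out a library can leave 2 libraries in a group, whose spread is then pooled with that of the other groups.

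The comparisons, tests, named genes, gene lists and most alternatives were chosen before the data were examined. Named genes were the targeted genes, for each comparison the 6 largest increases and 6 largest decreases among called genes with a mean of at least 10 CPM in the higher group and, except for the response differences, no overlap between replicates, and the 3 members of each described list with the smallest p. These genes may appear again in other comparisons. Genes without overlap between 3 and 3 libraries arise by chance in 10% of cases. In all 650 results of 297 genes were open to naming, of which 636 were called. Of 33 lists with 702 members, 33 members were absent from the table and 29 lists had enough measured members to be tested. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, with Benjamini-Hochberg adjustment over the 29 lists of a comparison. The test fry asked whether a list moved on balance in 1 direction, without setting it against other genes; its p is given where its verdict on a described list differs from that of camera. The medians of a list's difference from WT without and with LPS were computed after the results were seen.

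The tests were first run on simulated counts drawn from the real means and library sizes with 200 changed genes. For DKO against WT (14900 genes) edgeR recovered 49.3% of 1.5-fold, 85.1% of 2-fold and 97% of 4-fold changes, with 6.1% false among its calls. For the difference of the LPS responses of DKO and WT (14892 genes) it recovered 13.4%, 64.2% and 90.9%, with 8.9% false. For DKO against WT the false share was 8.4% for limma-voom and 15.8% for DESeq2, which exceeded the 5% level most. Each simulated gene had the same spread in all groups, and libraries of the same number were not paired. The real median residual SD on the log2 scale was 0.232 and 0.219 in the WT groups and 0.131 to 0.154 in the mutant groups. The recovered and false shares do not cover this inequality. In camera 5 of 100 random lists reached an unadjusted p under 0.05. The simulated genes were drawn independently, so this check cannot show how camera treats lists whose members vary together. Estimated correlations of the real lists reached 0.825.

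Whether replicate numbers pair the libraries of different groups was checked by the correlation of their deviations from the group mean. The correlations exceeded 0.1 for all 3 numbers in the comparisons of untreated genotypes and for LPS in WT (0.35, 0.55 and 0.44), and not for LPS in DKO (0.25, 0.06 and 0.14), LPS in Acox1KO (0.23, 0.02 and 0.12). The response differences join the paired WT libraries with mutant libraries that did not pair. A fit with replicate number as a block was run as an alternative throughout, and a block within each genotype for the comparisons with LPS. The other alternatives were RLE size factors, scaling by total count, no filter and a stricter filter of 10 CPM in 3 libraries, DESeq2, limma-voom, a fit to the compared groups alone, a test against a 1.5-fold change and leaving out each library. Median residual SD on the log2 scale was 0.232 in WT and 0.131 in DKO cells, and the lowest correlation between replicates of a group was 0.9829. Genes with no read in any library are absent from the table, and read sequences were not analysed here.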

Results

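RNA sequencing counted transcripts in BV-2 cells, an immortalised line of mouse microglia, the resident macrophages of the brain. The line was used as wild type (WT), as a double knockout of the peroxisomal fatty acid transporters Abcd1 and Abcd2 (DKO), and as a knockout of Acox1 (Acox1KO), the first oxidase of peroxisomal β-oxidation. Each genotype was cultured with vehicle alone or with 1 µg/ml lipopolysaccharide (LPS), a bacterial Toll-like receptor 4 ligand, for 24 h. The 6 groups held 3 libraries each, 18 in all. The libraries held 21154160 to 42204619 counted reads and found reads for 18470 to 20957 genes each. Mitochondrially encoded genes took 0.34% to 1.34% of the counts of a library. Of 28769 genes in the deposited table, 15131 had enough reads to be tested. The labels describe 3 independent batches of cells per genotype and do not mention more than 1 mutant line per genotype, so the p-values measure the spread between these cultures and not between independently made mutants. Values are CPM (counts as parts of the library's scaled total) ± SD with n = 3 and log2 fold changes with their standard error (SE). Adjusted p-values of genes are Benjamini-Hochberg values of edgeR's quasi-likelihood test, those of gene lists come from camera, which sets a list against other genes, with a preset correlation between genes, and calls use a threshold of 0.05. Ranges behind ratios of very low counts, and the limits used where a group had no counts, cover counting error only.

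WT cells stood apart from both mutants on the first principal component, which carried 47% of the variance. The next components, with 20.9% and 19.1%, each mixed treatment and genotype. On both, LPS cultures lay below untreated cultures of the same genotype. At the same treatment DKO lay below Acox1KO cells on the second component and above them on the third. The fourth component, with 3%, set the WT replicate 2 libraries apart from the other WT libraries.

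**Figure D1:**
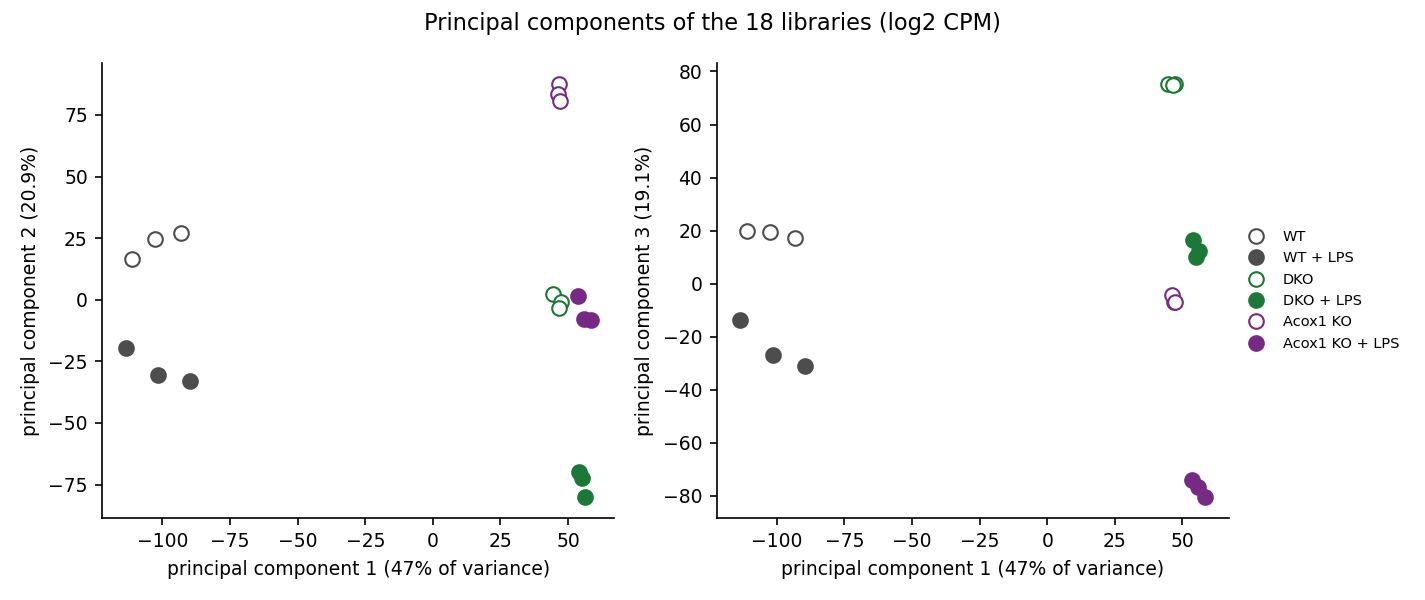
Principal components of the 18 libraries from log2 CPM, with the first component on the horizontal axis (47% of the variance) against the second (20.9%) and the third (19.1%), and 1 point per library coloured by group. The 3 libraries of each group lie close together and WT lies apart from both mutants on the first component.

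The targeted genes were examined first in every library. Abcd2 (ENSMUSG00000055782, chromosome 15, 91145871 to 91191799 on mm10) stood at 275 ± 110 CPM in untreated WT cells and 18.9 ± 6.8 CPM in DKO cells, a log2 fold change of −3.87 (SE 0.39, edgeR adjusted p = 5.83e-07). All 3 DKO libraries lay below all 3 WT libraries. Acox1KO cells held 199 ± 64 CPM of Abcd2, which did not pass the same test against WT (log2 fold change −0.47, edgeR adjusted p = 0.283) but did with the replicate block (−0.44, edgeR adjusted p = 0.0299). Abcd1 (ENSMUSG00000031378, chromosome X, 73716597 to 73738534) kept its transcript in DKO cells, with 58.2 ± 9.3 CPM in WT and 54.3 ± 2.0 CPM in DKO (edgeR adjusted p = 0.536). It was higher in Acox1KO cells, at 109 ± 5.9 CPM (log2 fold change 0.90, edgeR adjusted p = 1.34e-05). Acox1 (ENSMUSG00000020777, chromosome 11, 116171888 to 116199045) rose from 99.9 ± 28 CPM in WT to 160 ± 10 CPM in DKO and 157 ± 26 CPM in Acox1KO cells (log2 fold changes 0.68 and 0.65, edgeR adjusted p = 0.00429 and 0.00642). A frameshift can leave a transcript in place, so the levels of Abcd1 and Acox1 neither bear out nor contradict the labels of the knockouts. LPS lowered Abcd2 in every genotype, to 94.3 ± 22 CPM in WT, 1.68 ± 0.83 in DKO and 7.15 ± 2.9 in Acox1KO cells, with log2 fold changes of −1.55, −3.45 and −4.80. The edgeR adjusted p of the change in WT was 0.00835 and became 0.0572, with a log2 fold change of −1.25, without WT replicate 1.

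**Figure D2:**
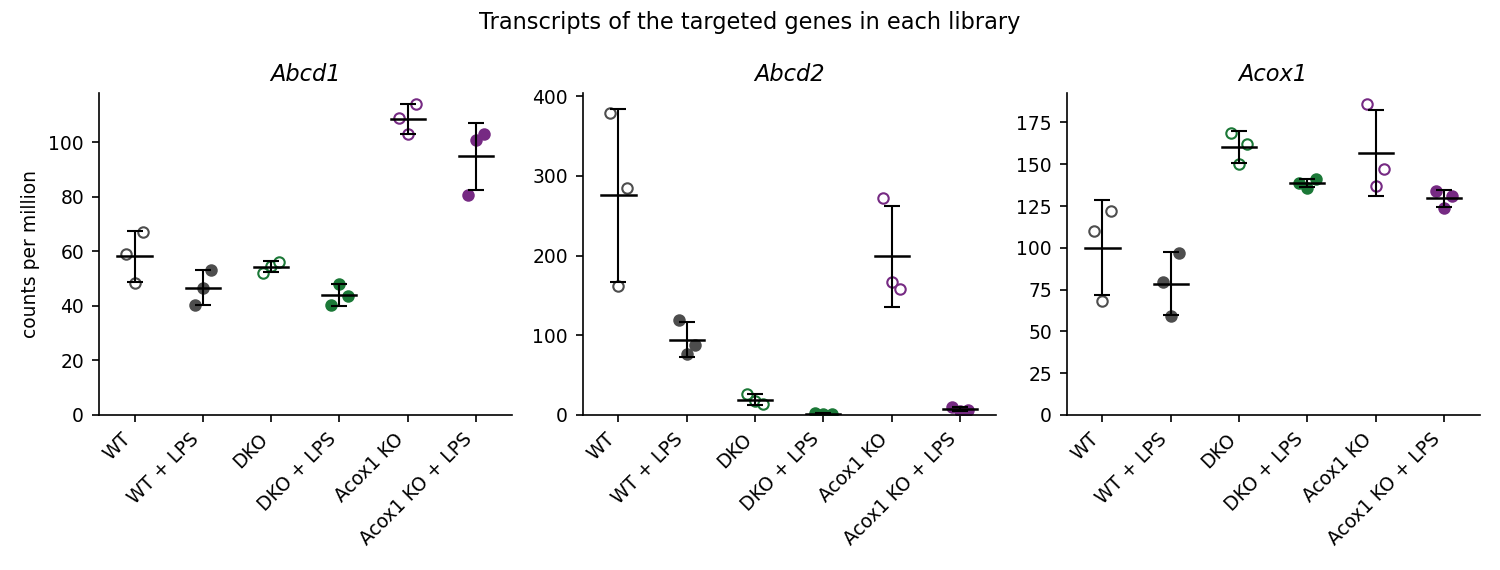
CPM of Abcd1, Abcd2 and Acox1 in each of the 18 libraries, with points for libraries (open untreated, filled LPS) and bars for the mean ± SD of each group of 3. Abcd2 averaged 275 CPM in untreated WT and 18.9 CPM in untreated DKO cells, while Abcd1 and Acox1 kept their transcripts in the lines in which they were targeted.

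The comparison of untreated DKO with WT cells asked what accompanies the loss of both transporters at rest. DKO cells differed from WT in 8064 genes, 53.3% of those tested, with 3818 higher and 4246 lower, and 3472 of them differed by at least 2-fold. DKO cells expressed more of the genes of lysosomes and of disease-associated microglia, and more p53 target genes. The lists of the cell cycle, of the integrated stress response and of fatty acid synthesis, elongation and desaturation were lower. None of these list calls held with an estimated correlation, where the adjusted p were 0.186 to 0.83. The genes with the largest differences were present at high levels in one line and close to absent in the other. Tspan7 rose from 2.09 ± 0.62 to 161 ± 13 CPM (78.1-fold, edgeR adjusted p = 5.03e-12), and Rxfp1, Mid2 and Spink5 rose by 6.81, 6.32 and 5.49 on the log2 scale. Stk26, Tmeff1 and Lamtor4 had no counts in the DKO libraries and were at least 1290-fold, 1190-fold and 721-fold lower than in WT. Dhcr24, the last enzyme of cholesterol synthesis, was lower by a ratio of 7820 (95% counting interval 2160 to 64600).

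Of 24 measured genes of disease-associated microglia, 20 were higher in DKO cells and 1 was lower (camera adjusted p = 3.97e-06; 0.564 with an estimated correlation). Lilrb4a, an inhibitory receptor, rose from 25.5 to 88.0 CPM, and the integrin gene Itgax from 132 to 386 CPM. The cathepsin genes Ctsb and Ctsl, which the list shares with the lysosomal list, rose from 1320 ± 180 to 3360 ± 110 CPM and from 1090 ± 40 to 2400 ± 63 CPM. Of 32 lysosomal genes, 24 were higher and none lower, and 25 were higher when adjusted over the list alone (camera adjusted p = 0.0001; 0.83 with an estimated correlation). Atp6ap1, an accessory part of the proton pump, rose by 0.84 on the log2 scale. Of 21 p53 target genes, 13 were higher and 2 lower (camera adjusted p = 0.00182; 0.247 with an estimated correlation), among them Trp53inp1 (33.3 to 174 CPM), the p53 ligase gene Mdm2 (95.4 to 223 CPM) and Phlda3 (36.7 to 115 CPM). Of 32 cell cycle genes, 23 were lower and none higher (camera adjusted p = 9.13e-05; 0.788 with an estimated correlation). The cyclin gene Ccnd2 was nearly lost, from 270 ± 61 to 0.79 CPM (log2 fold change −8.37, edgeR adjusted p = 3.05e-13), Ccnd1 went from 628 to 205 CPM, and the ribonucleotide reductase gene Rrm2 fell by 1.43 on the log2 scale.

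Among 25 genes of the integrated stress response, 15 were lower and 4 higher, or 16 and 5 adjusted over the list alone (camera adjusted p = 0.00182; 0.564 with an estimated correlation). The amino acid transporter gene Slc7a5 went from 324 to 129 CPM and the mitochondrial folate gene Mthfd2 from 213 to 72.2 CPM. Of 24 genes of fatty acid synthesis, elongation and desaturation, 10 were lower and 5 higher (camera adjusted p = 0.0144; 0.186 with an estimated correlation). The desaturase genes Scd1 and Fads2 were nearly silent, while Scd2 (2950 CPM) and Fads1 (322 CPM) kept their expression. Scd1 went from 293 ± 37 to 0.0467 CPM (log2 fold change −12.43, edgeR adjusted p = 1.74e-15), and Fads2 was lower by a ratio of 6420 (95% counting interval 2200 to 31200), with a log2 fold change of −12.46 that became −13.36 without DKO replicate 3. The elongase gene Elovl7 rose from 5.11 to 29.4 CPM. The lists that describe the targeted pathway did not stand apart from other genes. Of 20 genes of peroxisomal β-oxidation 6 were higher and 5 lower (camera adjusted p = 0.809), of 16 peroxisome biogenesis genes 8 were higher and 2 lower (0.316), and of 21 genes of mitochondrial fatty acid oxidation 10 were higher and 4 lower (0.306). Tested against no change with fry, the last 2 lists were higher on balance (adjusted p = 0.00729 and 0.0181), and peroxisomal β-oxidation did not pass (0.201). The peroxisomal β-oxidation list contains the targeted genes Abcd1, Abcd2 and Acox1 and was not tested without them. Here Abcd2 is among its lower and Acox1 among its higher members. The lipid droplet coat gene Plin2 rose from 130 to 386 CPM.

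Single genes of microglial identity and immune function also differed. Of 31 inflammatory genes 12 were lower and 6 higher, 14 and 6 adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.296; 0.916 with an estimated correlation) but was lower on balance against no change (fry adjusted p = 0.0181). Tnf went from 82.0 ± 18 to 13.7 ± 2.3 CPM (log2 fold change −2.58, edgeR adjusted p = 5.23e-09), the LPS co-receptor gene Cd14 from 238 to 55.1 CPM and the inhibitor gene Nfkbia from 81.1 to 32.2 CPM. The chemokine gene Ccl9 rose from 72.3 to 454 CPM. The complement gene C1qb fell from 113 to 6.78 CPM (log2 fold change −4.05, edgeR adjusted p = 1.01e-09), and the class I gene H2-K1 from 319 to 108 CPM. Of 19 homeostatic microglial genes 9 were lower and 3 higher (camera adjusted p = 0.16; fry adjusted p = 6.87e-05, lower), with P2ry12 at 4.14 CPM in WT and 0.35 CPM in DKO cells. Markers of other brain cells went both ways. Of 3 astrocyte markers 2 were higher (camera adjusted p = 0.17; fry adjusted p = 0.000158), with Slc1a2 at 0.157 CPM in WT and 2.4 CPM in DKO cells and Aldh1l1 at 2.28 and 5.03 CPM, the latter not called without WT replicate 2 (edgeR adjusted p = 0.0507). Map2, a neuronal marker, averaged 24.3 ± 3.6 CPM in WT and 0.0449 CPM in DKO cells (log2 fold change −9.13, which became −8.42 without DKO replicate 2 and −10.4 without DKO replicate 3), and the oligodendrocyte marker Mbp 46.3 ± 6.4 and 4.52 ± 0.71 CPM.

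The comparison of untreated Acox1KO with WT cells asked the same of the loss of the oxidase. Here 7666 genes differed, 50.7% of those tested, with 3610 higher and 4056 lower, and 3189 differed by at least 2-fold. As in DKO cells, lysosomal genes and genes of disease-associated microglia were higher and the lists of the cell cycle, the stress response and fatty acid synthesis, elongation and desaturation were lower. Interferon-stimulated genes, class I antigen presentation and oxidative phosphorylation were higher as well, and resting cytokine transcripts were lower. None of these list calls held with an estimated correlation, where the adjusted p were 0.147 for fatty acid synthesis and 0.69 for the others. Without passing, interferon-stimulated and oxidative phosphorylation genes were also higher in DKO cells by their median (0.51 and 0.25, camera adjusted p = 0.17 and 0.108). The inflammatory list had a median of −0.99 there. Between the mutants the interferon-stimulated, oxidative phosphorylation and inflammatory lists did not pass (camera adjusted p = 0.0812, 0.897 and 0.277). Rbp7, a retinol-binding protein gene, had no counts in WT and was at least 336-fold higher at 10.5 CPM. Iqsec3 and Sema3b rose by 3.94 and 3.85 on the log2 scale. Chil3, which encodes a chitinase-like protein of alternatively activated macrophages, averaged 277 ± 220 CPM in WT and 8400 ± 6200 CPM in Acox1KO cells (edgeR adjusted p = 0.00432), with no adjusted p from DESeq2. Its log2 fold change of 4.92 became 4.13 without Acox1KO replicate 1. Dhcr24, Ctnnd2, Qsox1 and Cbs had no counts in Acox1KO cells and were at least 5340-fold, 1900-fold, 1550-fold and 1410-fold lower.

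Of the 32 lysosomal genes 30 were higher in Acox1KO cells and none lower (camera adjusted p = 2.29e-08; 0.69 with an estimated correlation). Ctsb rose from 1320 to 3370 ± 440 CPM, the galactosylceramidase gene Galc from 36.9 to 99.5 CPM and the mannosidase gene Man2b1 from 193 to 377 CPM. Of the 24 genes of disease-associated microglia 18 were higher and 2 lower, and 19 were higher adjusted over the list alone (camera adjusted p = 6.52e-05; 0.69 with an estimated correlation). Itgax and Lilrb4a rose by 1.36 and 1.41 on the log2 scale. Of 35 interferon-stimulated genes 18 were higher and none lower, 19 adjusted over the list alone (camera adjusted p = 0.00219; 0.69 with an estimated correlation). The transcription factor gene Irf9 rose from 10.9 to 30.0 CPM and the antiviral gene Oas2 from 4.46 to 14.7 CPM. Of 21 genes of class I presentation 16 were higher and 1 lower, 18 higher adjusted over the list alone (camera adjusted p = 0.00852; 0.69 with an estimated correlation), among them the immunoproteasome gene Psmb8 (73.9 to 173 CPM). Of 29 genes of nuclear-encoded oxidative phosphorylation 14 were higher and none lower (camera adjusted p = 0.0396; 0.69 with an estimated correlation), with the ATP synthase gene Atp5c1 at 336 CPM in WT and 558 CPM in Acox1KO cells.

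Of the 25 stress response genes 15 were lower and 1 higher in Acox1KO cells, 16 and 3 adjusted over the list alone (camera adjusted p = 0.00852; 0.69 with an estimated correlation). Mthfd2 went from 213 to 87.3 CPM and the proline synthesis gene Pycr1 fell by 2.89 on the log2 scale. Of the 32 cell cycle genes 20 were lower and 2 higher (camera adjusted p = 0.0159; 0.69 with an estimated correlation), with Ccnd2 going from 270 to 0.425 CPM and Ccnd1 from 628 to 264 CPM. Of the 24 genes of fatty acid synthesis 8 were lower and 5 higher (camera adjusted p = 0.00991; 0.147 with an estimated correlation). Scd1 went from 293 to 0.27 CPM, and the elongase gene Elovl6 from 121 to 38.5 CPM. Of 31 inflammatory cytokine, chemokine and mediator genes 13 were lower and 4 higher (camera adjusted p = 0.0309; 0.69 with an estimated correlation and 0.0915 with replicate number as a block), and the list was lower against no change (fry adjusted p = 0.000654). Tnf went from 82.0 to 9.99 ± 2.8 CPM (log2 fold change −3.03, edgeR adjusted p = 7.75e-10), Ccl9 from 72.3 to 13.1 CPM and Cd14 from 238 to 19.9 CPM, while the mannose receptor gene Mrc1 rose from 390 to 1750 CPM. Of 4 measured oligodendrocyte markers 2 were lower (camera adjusted p = 0.041; 0.412 with an estimated correlation and 0.0705 with the block), with Mbp at 46.3 CPM in WT and 1.53 ± 0.46 CPM in Acox1KO cells. Of the 20 genes of peroxisomal β-oxidation 11 were higher and 3 lower, with a median log2 fold change of 0.36 but a mean of −0.40 (camera adjusted p = 0.308), of the 16 biogenesis genes 7 were higher and none lower (0.225), and of the 21 genes of mitochondrial fatty acid oxidation 10 were higher and 3 lower (0.16). As in DKO cells, the last 2 lists were higher on balance with fry (adjusted p = 0.0044 and 0.00938), and peroxisomal β-oxidation did not pass (0.115). The targeted genes Abcd1 and Acox1 are among the higher members of the peroxisomal β-oxidation list. All 3 astrocyte markers were higher (camera adjusted p = 0.185; fry adjusted p = 0.000654), with Aldh1l1 at 2.28 CPM in WT and 9.74 CPM in Acox1KO cells. Slc1a2 was not called without WT replicate 1, WT replicate 3 or Acox1KO replicate 2 (edgeR adjusted p = 0.108, 0.0576 and 0.139), nor Aldoc without WT replicate 2, Acox1KO replicate 1 or Acox1KO replicate 3 (0.0929, 0.0508 and 0.0614).

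The calls of both mutants against WT were then compared. Both mutants were higher than WT in 2189 genes and lower in 2813, 5002 together, against 911 and 1138 for independent choices, and 420 genes went opposite ways. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.71. Shared WT libraries alone give such a relation, and in 20 simulations without any change they gave an r of 0.64. The share of genes with the same sign in both comparisons was 74.3%, against 74.7% in the simulations. The covariance of the fold changes, 2.15, exceeded the simulated 0.0584 by 2.09. In the same simulations at most 1 gene was called in the same direction in both mutants, against 5002 here. The simulated mutants had the WT means, and the simulations called 0.2 genes on average for DKO against WT. Few shared calls were therefore likely from the start, so this count does not show what shared WT libraries add to the overlap. The 3 WT libraries were too few to be divided between the comparisons. How far shared controls add to the calls of genes that do differ was therefore not measured.

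The direct comparison of both mutants asked which changes differ between them. Acox1KO and DKO cells differed in 5313 genes, 35.1% of those tested, with 2612 higher and 2701 lower in Acox1KO cells and 1976 at least 2-fold apart. p53 target genes were lower in Acox1KO cells. Class I presentation, complement and phagocytosis genes and cholesterol synthesis genes were higher, calls that were lost with an estimated correlation (adjusted p = 0.734, 0.725 and 0.734). Spink5 and Rgs18 had no counts in Acox1KO cells and were at least 877-fold and 357-fold lower than in DKO cells. Celf4 was higher by 7.49 on the log2 scale, and Chil3 by 9.97 with no adjusted p from DESeq2 and 9.16 without Acox1KO replicate 1. Eda2r, a p53 target gene for a death receptor, went from 49.5 to 0.108 CPM (log2 fold change −8.81). Of the 21 p53 target genes 17 were lower and none higher (camera adjusted p = 4.91e-11; 0.00515 with an estimated correlation), with 1 higher adjusted over the list alone. Mdm2 went from 223 to 80.6 CPM (log2 fold change −1.47, edgeR adjusted p = 1.47e-08) and Trp53inp1 from 174 to 56.8 CPM. Against WT, 10 of the 21 genes were lower and 2 higher in untreated Acox1KO cells. That list did not pass against other genes (camera adjusted p = 0.158) but was lower against no change (fry adjusted p = 6.79e-05).

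Of the 21 class I genes 15 were higher in Acox1KO than in DKO cells and none lower (camera adjusted p = 3.28e-07; 0.734 with an estimated correlation), with H2-K1 at 108 CPM in DKO and 318 CPM in Acox1KO cells. Psmb8 and Psmb10 were higher by 1.41 and 1.07 on the log2 scale. Of 25 phagocytosis, scavenger and complement genes 13 were higher and 2 lower, 3 lower adjusted over the list alone (camera adjusted p = 3.82e-06; 0.725 with an estimated correlation). C1qb rose from 6.78 to 287 CPM (log2 fold change 5.41, edgeR adjusted p = 1.48e-10), the central complement gene C3 from 58.5 to 860 CPM and the scavenger receptor gene Cd36 from 10.5 to 105 CPM. Of 23 cholesterol synthesis and uptake genes 16 were higher and 1 lower (camera adjusted p = 1.52e-05; 0.734 with an estimated correlation), among them Hsd17b7 (17.8 to 37.9 CPM) and Mvd, which rose by 1.37 on the log2 scale. Of the 20 genes of peroxisomal β-oxidation 8 were higher and none lower (camera adjusted p = 0.0812, and 0.0356 with the replicate block; fry adjusted p = 0.0251), among them the carnitine acetyltransferase gene Crat, which rose by 0.93 on the log2 scale. Abcd1 and Abcd2, the genes targeted in DKO cells, belong to this list, which was not tested without them. With the block the cell cycle list also passed (camera adjusted p = 0.0469, against 0.0812 without it). With an estimated correlation neither the peroxisomal β-oxidation nor the cell cycle list passed (camera adjusted p = 0.971 for both). Ccl9 was lower, at 13.1 against 454 CPM, as was the lipoprotein lipase gene Lpl, at 563 against 1480 CPM, and Mrc1 was higher, at 1750 against 213 CPM.

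The next comparisons asked what LPS changes in each genotype. In WT cells 1721 genes changed, 11.4% of those tested, with 858 higher and 863 lower, and 849 changed at least 2-fold. Cytokines, chemokines, interferon-stimulated genes and their feedback inhibitors rose, together with antioxidant genes and class I presentation, the last not with an estimated correlation (adjusted p = 0.247). The complement genes C1qa and C1qc and the alternative activation marker Arg1 fell, while the phagocytosis, scavenger and complement list had 7 genes rising and 7 falling of 25 (camera adjusted p = 0.958). The replicate numbers paired the WT libraries, and 2646 genes changed with replicate number as a block and 3528 with a block within each genotype, while a fit to the WT libraries alone called 516 (369 higher and 147 lower). The balance of directions rested on single libraries, with 1353 genes lower without WT replicate 2, 535 and 528 without WT replicates 1 and 3, and 566 without WT_LPS replicate 1. Of the 31 inflammatory genes 20 rose and none fell, 23 adjusted over the list alone (camera adjusted p = 4.54e-41; 0.0103 with an estimated correlation). The acute phase genes Lcn2 and Saa3 rose from 2.45 to 294 ± 140 CPM and from 19.3 to 1800 ± 930 CPM (log2 fold changes 6.97 and 6.54, edgeR adjusted p = 2.35e-08 and 4.61e-08), and Tnf from 82.0 to 386 ± 35 CPM. Of the 35 interferon-stimulated genes 32 rose, 33 adjusted over the list alone (camera adjusted p = 3.55e-47; 0.0476 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose from 0.462 to 56.5 CPM, and Oas2 and Irf9 rose by 3.23 and 1.74 on the log2 scale.

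Of 23 feedback inhibitors and anti-inflammatory genes 14 rose and 3 fell in WT cells, 15 rising adjusted over the list alone (camera adjusted p = 2.32e-17; 0.0476 with an estimated correlation). The signalling inhibitor genes Irak3 and Tnip1 rose by 2.73 and 1.52 on the log2 scale. Of 29 genes of Toll-like receptor 4 signalling 7 rose and 1 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.000564; 0.0476 with an estimated correlation), with Tlr2 rising by 1.82 and Cd14 by 1.42 on the log2 scale. Of 27 antioxidant genes of the NRF2 pathway 11 rose and none fell, 13 and 1 adjusted over the list alone (camera adjusted p = 2.23e-10; 0.0476 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 25 to 202 CPM (log2 fold change 3.01, edgeR adjusted p = 1.67e-10). Of the 21 class I genes 13 rose, 17 adjusted over the list alone (camera adjusted p = 1.53e-10; 0.247 with an estimated correlation). None of 7 mitochondrially encoded genes passed the threshold alone, and as a list they fell (camera adjusted p = 0.0401; 0.986 with an estimated correlation; fry adjusted p = 0.141). The arginase gene Arg1, a marker of alternative activation, went from 766 ± 630 to 2.06 CPM (log2 fold change −8.57, edgeR adjusted p = 0.000294), or −9.24 without WT_LPS replicate 1. C1qa and C1qc fell by 4.47 and 3.39 on the log2 scale, the apolipoprotein gene Apoe by 1.43, and Cytip and Mgl2 by 4.29 and 2.93.

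In DKO cells LPS changed 4194 genes, 27.7% of those tested, with 2338 higher and 1856 lower, and 1590 changed at least 2-fold. The share of rising genes among them was 55.7%, and 43.1% when libraries were scaled by total count alone. Inflammatory, interferon-stimulated, class I and antioxidant genes rose as in WT cells. Genes of the integrated stress response rose as well, and mitochondrially encoded genes and genes of mitochondrial fatty acid oxidation fell. With an estimated correlation the interferon-stimulated and class I lists (adjusted p = 0.0519 for both) and these falling lists (0.438 and 0.591) no longer passed. Of the 31 inflammatory genes 28 rose and none fell, 29 adjusted over the list alone (camera adjusted p = 5.79e-43; 0.00622 with an estimated correlation). Lcn2 rose from 0.102 to 319 ± 47 CPM (log2 fold change 11.60, edgeR adjusted p = 6.24e-10) and Tnf from 13.7 to 422 ± 21 CPM (log2 fold change 4.94, edgeR adjusted p = 2.9e-11). Of the 23 feedback genes 17 rose and 2 fell (camera adjusted p = 4.35e-20; 0.0289 with an estimated correlation), with Nfkbia rising from 32.2 to 288 CPM. Of the 29 genes of Toll-like receptor 4 signalling 10 rose and 5 fell (camera adjusted p = 0.00189; 0.0489 with an estimated correlation). Of the 35 interferon-stimulated genes 33 rose (camera adjusted p = 2.88e-38; 0.0519 with an estimated correlation), with Ifit1 rising from 2.26 to 161 CPM. Of the 21 class I genes 20 rose (camera adjusted p = 2.19e-19; 0.0519 with an estimated correlation), with H2-K1 rising from 108 to 524 CPM. Of 13 class II genes 3 rose and 1 fell (camera adjusted p = 0.0266; 0.604 with an estimated correlation), and the costimulatory receptor gene Cd40 rose from 2.36 to 52.2 CPM.

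Of the 27 antioxidant genes 20 rose in DKO cells and none fell (camera adjusted p = 3.55e-17; 0.0201 with an estimated correlation). Slc7a11 rose from 29.8 to 608 CPM (log2 fold change 4.35, edgeR adjusted p = 3.95e-13), and the mitochondrial dismutase gene Sod2 and the NADPH source G6pdx rose by 1.55 and 0.96 on the log2 scale. Of the 25 stress response genes 17 rose and none fell (camera adjusted p = 1.54e-10; 0.0289 with an estimated correlation), among them Mthfd2 (72.2 to 173 CPM) and the stress regulator gene Nupr1 (4.97 to 53.1 CPM). All 7 mitochondrially encoded genes fell (camera adjusted p = 0.00108; 0.438 with an estimated correlation), with mt-Nd1 going from 3750 to 1420 CPM. Of the 21 genes of mitochondrial fatty acid oxidation 8 fell and 1 rose (camera adjusted p = 0.0266; 0.591 with an estimated correlation), with the dehydrogenase gene Acadm falling by 1.02 on the log2 scale. Gpr183, an oxysterol receptor gene, went from 23.4 to 0.628 CPM (log2 fold change −5.23, edgeR adjusted p = 1.16e-10). Arg1 went from 62.5 to 0.447 CPM (log2 fold change −7.08), a change that limma-voom did not call (adjusted p = 0.0945) and that became −7.75 without DKO_LPS replicate 1. Cytip and the cytidine deaminase gene Aicda fell by 2.89 and 2.99 on the log2 scale.

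In Acox1KO cells LPS changed 4748 genes, 31.4% of those tested, with 2700 higher and 2048 lower, and 1952 changed at least 2-fold. Rising genes made up 56.9% of these, and 40.1% with scaling by total count alone, which moved the median log2 fold change of all genes to −0.106. The same immune and antioxidant programmes rose, and cholesterol synthesis and oxidative phosphorylation genes fell. With an estimated correlation the interferon-stimulated and class I lists (adjusted p = 0.4 for both) and these falling lists (0.429 and 0.696) no longer passed. Of the 31 inflammatory genes 23 rose and 1 fell (camera adjusted p = 1.31e-28; 0.00929 with an estimated correlation). Lcn2 averaged 1880 ± 280 CPM with LPS against 0.027 CPM without, a ratio of 64100 (95% counting interval 21900 to 311000), with a log2 fold change of 15.81 that became 16.53 without Acox1KO replicate 3. Tnf rose from 9.99 to 712 ± 100 CPM (log2 fold change 6.15, edgeR adjusted p = 1.72e-12) and Ccl9 from 13.1 to 398 CPM. The complement factor gene Cfb had no counts without LPS and was at least 1190-fold higher with it. Of the 29 genes of Toll-like receptor 4 signalling 13 rose and 2 fell (camera adjusted p = 1.93e-06; 0.00929 with an estimated correlation), with Cd14 rising from 19.9 to 469 CPM and Tlr2 from 50.3 to 796 CPM. Of the 27 antioxidant genes 20 rose and none fell, 22 adjusted over the list alone (camera adjusted p = 2.47e-21; 0.00929 with an estimated correlation). Slc7a11 rose from 21.6 to 1120 CPM (log2 fold change 5.70, edgeR adjusted p = 1.17e-14), the glutathione reductase gene Gsr by 2.06 on the log2 scale and the ferritin gene Fth1 from 3750 to 18900 CPM.

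Of the 23 feedback genes 16 rose and 5 fell in Acox1KO cells (camera adjusted p = 1.5e-15; 0.0595 with an estimated correlation), with Nfkbia rising from 40.3 to 441 CPM. Of the 25 stress response genes 17 rose and 1 fell (camera adjusted p = 7.13e-07; 0.0923 with an estimated correlation), with Mthfd2 rising from 87.3 to 269 CPM. Of the 35 interferon-stimulated genes 33 rose (camera adjusted p = 7e-15; 0.4 with an estimated correlation), with Gbp2 and Ifit1 rising by 7.83 and 4.02 on the log2 scale. Of the 21 class I genes 18 rose (camera adjusted p = 6.33e-08; 0.4 with an estimated correlation), with H2-K1 rising from 318 to 943 CPM. Of the 23 cholesterol genes 14 fell and 1 rose (camera adjusted p = 5.86e-05; 0.429 with an estimated correlation), with the synthase gene Hmgcs1 going from 266 to 137 CPM and Cyp51 falling by 0.78 on the log2 scale. Of the 29 oxidative phosphorylation genes 11 fell, 12 adjusted over the list alone (camera adjusted p = 0.0344; 0.696 with an estimated correlation). Of the 7 mitochondrially encoded genes 5 fell, and all 7 adjusted over the list alone (camera adjusted p = 0.0344; 0.694 with an estimated correlation). Gpr183 went from 28.1 to 0.139 CPM (log2 fold change −7.62), Ccl24 fell by 6.63 on the log2 scale and Spp1 by 2.62. Arg1 went from 2250 ± 1300 to 1.09 CPM (log2 fold change −10.96, edgeR adjusted p = 2.07e-05), which became −10.37 without Acox1KO replicate 1 and −12.33 without Acox1KO_LPS replicate 1.

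**Figure D3:**
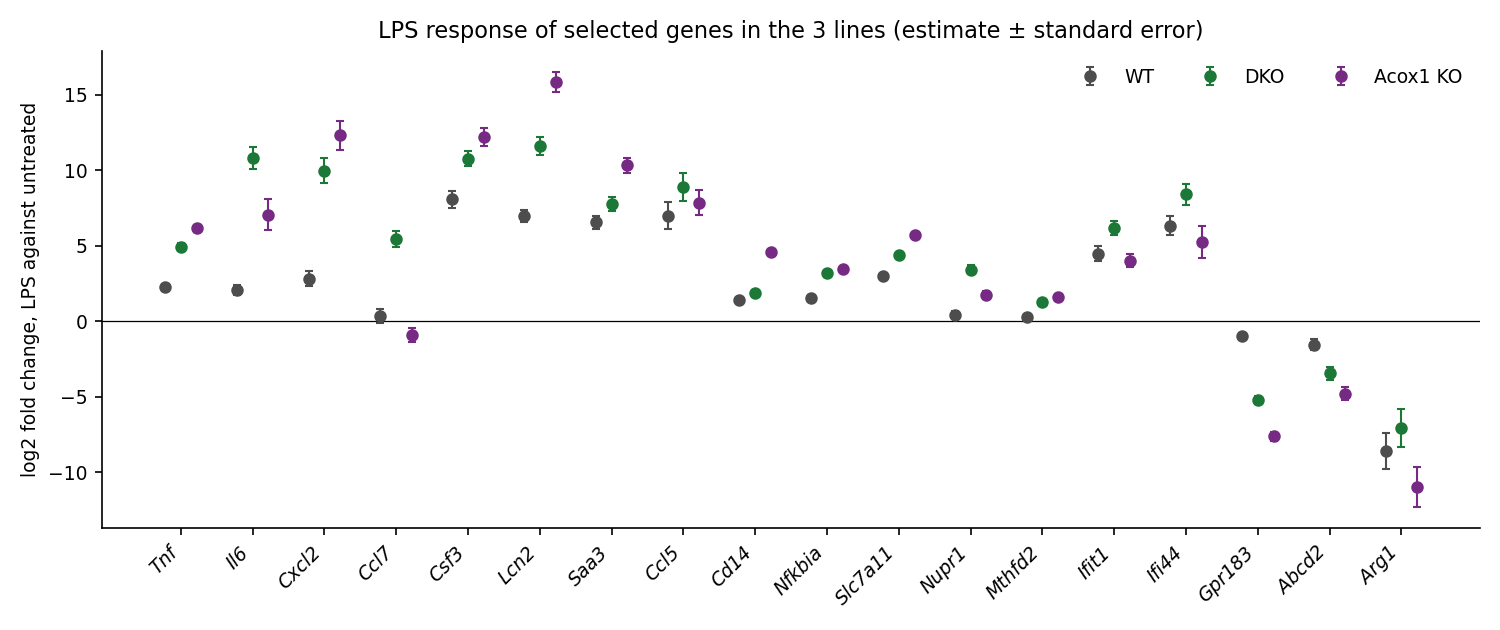
Log2 fold changes of 18 genes with LPS against untreated cells, as the edgeR estimate ± SE, in WT, DKO and Acox1KO cells (3 libraries per group). Tnf rose by 2.23 in WT, 4.94 in DKO and 6.15 in Acox1KO cells, and Gpr183 fell in the mutants.

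The test of the difference between the LPS responses of DKO and WT cells asked whether the response itself depends on the transporters. It passed for 512 genes, 3.4% of those tested, with 361 higher and 151 lower in DKO cells and 269 at least 2-fold apart. The lists of inflammatory mediators and of the integrated stress response had larger log2 fold changes in DKO cells. Antioxidant, feedback and class I genes also did so, and single genes such as Gpr183 and Mef2c fell further. With an estimated correlation the antioxidant (adjusted p = 0.0911), feedback and class I lists (0.164 for both) no longer passed. Of the 31 inflammatory genes 12 had a higher response and none a lower one, 19 adjusted over the list alone (camera adjusted p = 1.91e-20; 0.0316 with an estimated correlation). The response of Tnf was higher by 2.71 on the log2 scale (SE 0.25, edgeR adjusted p = 9.68e-06). With LPS its level was 422 ± 21 CPM in DKO and 386 ± 35 CPM in WT cells, so the difference lay mostly in the untreated cultures (13.7 against 82.0 CPM). The feedback genes Nfkbia and Tnfaip3 responded more by 1.59 and 2.09, within a list of 23 with 6 higher, 10 adjusted over the list alone (camera adjusted p = 1.8e-09; 0.164 with an estimated correlation). Of the 25 stress response genes 11 had a higher response and none a lower one, 14 adjusted over the list alone (camera adjusted p = 7.66e-16; 0.0214 with an estimated correlation). The median difference of the list, 0.62, was close in size to its median deficit in untreated DKO cells (−0.64), and with LPS its median lay −0.13 from WT on the log2 scale, so the difference lay mostly in the untreated cultures here too. The same medians of the feedback list were 0.93, −0.87 and 0.10. Nupr1, Atf5 and Aars responded more by 3.03, 1.58 and 0.79 on the log2 scale. Of the 27 antioxidant genes 8 had a higher response, 10 adjusted over the list alone (camera adjusted p = 8.12e-10; 0.0911 with an estimated correlation), with Slc7a11 higher by 1.34 (edgeR adjusted p = 0.000187) and G6pdx by 0.65. The median of this list lay −0.12 from WT without LPS and 0.40 with it.

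Of the 21 class I genes 4 had a higher response to LPS in DKO than in WT cells, 16 adjusted over the list alone (camera adjusted p = 1.54e-13; 0.164 with an estimated correlation), with H2-K1 and H2-Q4 higher by 1.59 and 2.08 on the log2 scale. Of the 13 class II genes 1 did, which was Cd40, higher by 3.48 (camera adjusted p of the list 0.000437, and 0.345 with an estimated correlation). The median of the class I list lay −0.18 from WT without LPS and 0.60 with it. The difference for H2-K1 lay mostly in the untreated cultures, where its level was lower than in WT cells. Of the 35 interferon-stimulated genes 1 passed alone, and 10 adjusted over the list alone (camera adjusted p = 8.12e-10; 0.547 with an estimated correlation; fry adjusted p = 0.138). Among 21 p53 target genes 1 had a higher and 1 a lower response, 3 and 3 adjusted over the list alone (camera adjusted p = 0.0287; 0.345 with an estimated correlation; fry adjusted p = 0.138). No mitochondrially encoded gene of 7 and no replication-dependent histone gene of 10 passed alone, while both lists did (camera adjusted p = 0.0168 and 0.0479; 0.57 and 0.547 with an estimated correlation, and 0.0808 for the histones with the block; fry adjusted p = 0.381 and 0.106). The response of Gpr183 was lower in DKO cells by a log2 difference of −4.25 (edgeR adjusted p = 6.8e-07), and those of the histone deacetylase gene Hdac9 and the transcription factor gene Mef2c by −2.30 and −1.90. The difference for Abcd2, −1.90, did not pass (edgeR adjusted p = 0.079), and passed with the replicate block (0.000683), the block within each genotype (0.00252) and DESeq2 (0.0339). The count of 512 genes depended on the fit and on single libraries. It was 307 with the compared groups alone, 1179 with the replicate block, 2114 with the block within each genotype and 877 with DESeq2. It was 336 without WT replicate 1, 873 without WT replicate 2, 286 and 337 without DKO replicates 2 and 3, and 317 and 278 without DKO_LPS replicates 1 and 3.

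The same test for Acox1KO cells asked whether the response depends on the oxidase. It passed for 777 genes, 5.1% of those tested, with 588 higher and 189 lower and 422 at least 2-fold apart. The count was 508 with the compared groups alone, 1532 with the replicate block and 2349 with the block within each genotype. Higher responses made up 75.7% of the calls, and 59.5% with scaling by total count alone. The response of inflammatory, antioxidant, receptor signalling and stress response genes was higher than in WT cells, and that of cholesterol synthesis genes was lower, the last not with an estimated correlation (adjusted p = 0.311). Of the 31 inflammatory genes 11 had a higher response and none a lower one, 14 adjusted over the list alone (camera adjusted p = 9.55e-17; 0.0353 with an estimated correlation). Tnf was higher by 3.92 on the log2 scale (SE 0.26, edgeR adjusted p = 3.88e-08) and Ccl9 by 3.31. Of the 27 antioxidant genes 12 had a higher response, 14 adjusted over the list alone (camera adjusted p = 2.82e-20; 0.0142 with an estimated correlation), with Slc7a11 higher by 2.69 (edgeR adjusted p = 2.4e-08), Gsr by 1.61 and Sod2 by 1.37. Of the 29 genes of Toll-like receptor 4 signalling 6 had a higher response, 8 adjusted over the list alone (camera adjusted p = 8.5e-06; 0.0142 with an estimated correlation), with Cd14 higher by 3.14 (edgeR adjusted p = 3.88e-08) and Tlr2 by 2.16. Of the 25 stress response genes 10 had a higher response, 15 adjusted over the list alone (camera adjusted p = 1.08e-09; 0.0353 with an estimated correlation), with Mthfd2, Asns and Aars higher by 1.32, 0.77 and 0.75. As in DKO cells, the median difference of this list (0.60) was close in size to its median deficit in untreated cells (−0.56), and with LPS its median lay 0.05 from WT. The median of the antioxidant list lay −0.09 from WT without LPS and 0.80 with it. That of the Toll-like receptor 4 list lay at −0.08 and 0.42. The response difference of Cd14 lay in the untreated cultures, where its level was far below that of WT cells.

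Of the 23 feedback genes 9 had a higher and 1 a lower response in Acox1KO than in WT cells, 11 and 1 adjusted over the list alone (camera adjusted p = 4.52e-08; 0.232 with an estimated correlation), with Nfkbia higher by 1.89 on the log2 scale. Of the 23 cholesterol genes 4 had a lower response, 5 adjusted over the list alone (camera adjusted p = 3.27e-07; 0.311 with an estimated correlation), with Cyp51, Hmgcs1 and Stard4 lower by log2 differences of −0.70, −0.63 and −0.47. The median of this list lay 0.33 from WT without LPS and −0.01 with it. Of the 21 class I genes 1 had a higher response and of the 29 oxidative phosphorylation genes none differed alone (camera adjusted p = 0.0194 for both; 0.95 with an estimated correlation; fry adjusted p = 0.257 and 0.62). The class I gene was H2-K1 (log2 difference 0.88), whose call was lost when any 1 of Acox1KO replicates 1 and 2, Acox1KO_LPS replicates 2 and 3, WT replicate 3 or WT_LPS replicate 1 was left out (edgeR adjusted p = 0.0514, 0.0633, 0.0511, 0.0777, 0.0517 and 0.05). The complement receptor gene C5ar1 responded more by 2.65 and the fatty acid receptor gene Gpr84 by 3.56, and the response of the peroxisomal catalase gene Cat was higher by 0.80. Gpr183 fell more than in WT cells, by a log2 difference of −6.64 (edgeR adjusted p = 8.98e-09), and so did Abcd2 (−3.25, edgeR adjusted p = 0.000989). Both mutants had a higher response than WT in 157 genes and a lower one in 38, 195 together, against 14 and 2 for independent choices, and 6 genes went opposite ways. Across genes the differences had a Pearson r of 0.43, against 0.63 in 20 simulations without any change that shared the WT libraries. The covariance was 0.261 against a simulated 0.112, an excess of 0.148. The simulations called at most 1 gene in the same direction in both mutants, but only 0.6 genes on average for the DKO difference. That low count was likely from the start and decides nothing about the overlap.

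**Figure D4:**
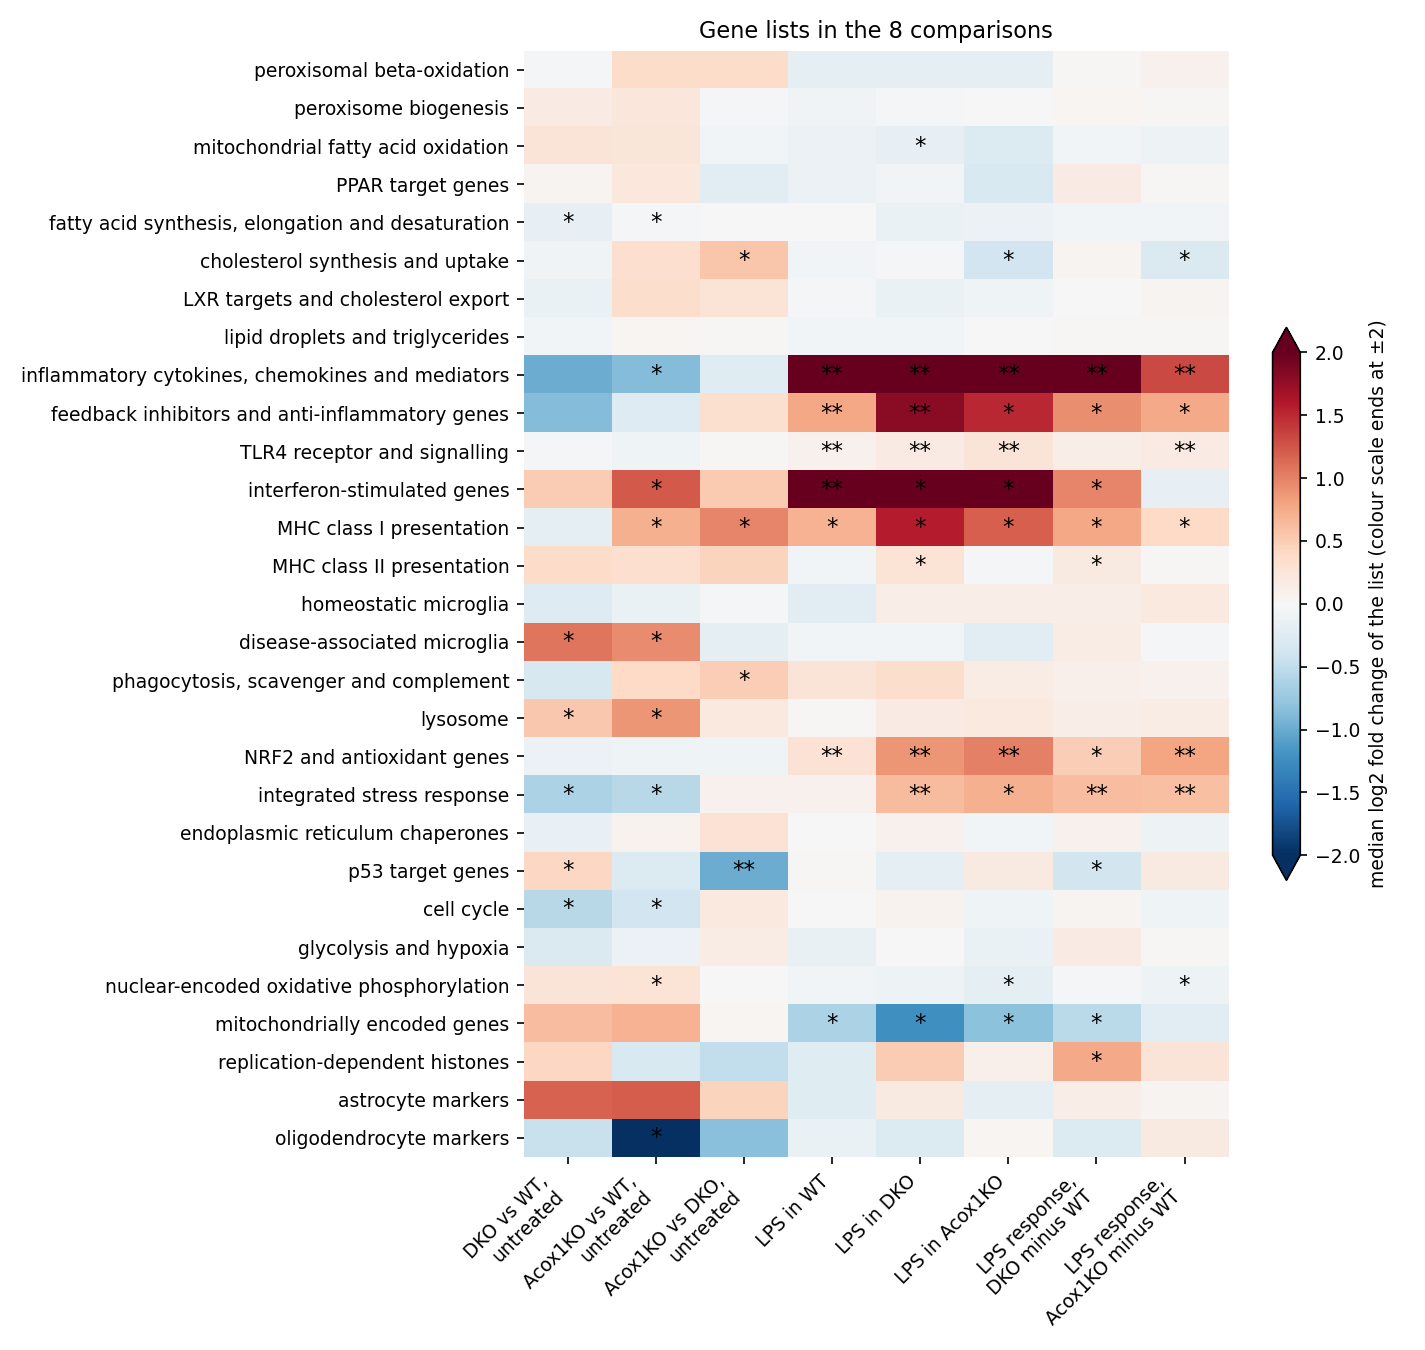
Median log2 fold change of the members of 29 gene lists (vertical axis) in the 8 comparisons (horizontal axis), in colour from −2 to 2, with 1 asterisk where camera passed with a preset correlation and a pair of them where it also passed with an estimated one. Of 232 tests 65 passed with the preset and 20 with the estimated correlation, most of these in the LPS comparisons.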

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

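The tests for a mislabelled library, for the share of a response difference that lies in untreated cultures and for a weaker stimulus, and the omission of both WT replicate 2 libraries, were chosen after the results were seen. The LPS response differed from that of WT cells in 512 genes in DKO and 777 genes in Acox1KO cells. In both cases 9 of 100 splits of the 12 libraries, the real one included, called as many genes, so by this count chance is not excluded. The highest other splits called 6764 and 7036 genes. This points to a structure of the samples, because all such splits came from the 54 that gave untreated and LPS groups an unequal mix of genotypes, which turns genotype differences into differences of response. The 45 splits with an equal mix called 0 genes at most. These splits put libraries of both genotypes in every group, which widens the spread within groups. Few or no calls were therefore likely from the start, and their 0 decides nothing. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05, and only 1 split of each, the real one, called as many genes. The real counts were 8064, 7666 and 5313 for the untreated genotypes and 1721, 4194 and 4748 for LPS in WT, DKO and Acox1KO cells. The highest other split called 1555 genes for LPS in WT, with both replicate 2 libraries on 1 side, and 0 in the other 5 comparisons.

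Among called genes with a mean of at least 10 CPM in the highest of the compared groups and an assigned name, those with the largest differences of LPS response from WT were the following, on the log2 scale. In DKO cells they were Cxcl2 7.18, Cxcl3 6.25, Ifi211 5.63, Ccl7 5.07, Lamb3 5.05 and Cd69 4.74 upward, and Gpr183 −4.25, Ccr5 −3.42, Plppr3 −3.15, Hdac9 −2.30, Dgkg −2.28 and Cx3cr1 −2.15 downward. In Acox1KO cells they were Cxcl2 9.5, Lcn2 8.84, Ccrl2 7.33, Cxcl3 7.06, Tnfrsf9 6.41 and Cd69 6.07 upward, and Gpr183 −6.64, Cxcr2 −5.37, Ccr5 −4.62, Tgif2 −4.07, Mylk −4.07 and Abcd2 −3.25 downward. Cxcl3 in both mutants and Cd69 in Acox1KO cells had no counts in the untreated mutant, so their values depend on the prior count. In DKO cells Cxcl2 became 6.28 without WT replicate 1, 11.29 without DKO replicate 1 and 6.46 without DKO replicate 2. Ccl7 became 4.34 without WT replicate 1, Cd69 6.64 without DKO replicate 1, Ifi211 6.28 without DKO replicate 3 and Plppr3 −4.57 without DKO_LPS replicate 1. Cxcl3 lost its call in DKO cells without WT replicate 1, any DKO replicate or DKO_LPS replicate 1, with edgeR adjusted p of 0.0548, 0.0749, 0.0985, 0.07 and 0.0665. In Acox1KO cells Cxcl2 became 8.60 without WT replicate 1, 12.13 without Acox1KO replicate 1 and 8.86 without Acox1KO replicate 3. Without Acox1KO replicate 3 Lcn2 became 9.56 and Ccrl2 6.69, without Acox1KO replicate 1 Cxcr2 −4.78, without Acox1KO replicate 2 Mylk −3.45, and without Acox1KO_LPS replicate 1 Ccr5 −5.65 and Tgif2 −6.05. limma-voom did not call Ccrl2 (adjusted p = 0.0717).

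In a first pattern, 35 genes, 31 of them protein coding, exceeded 10 CPM in every WT library and stayed under 0.3 CPM in every mutant library, among them Tuba4a, Dhcr24, Slc16a3 and Mga with WT means of 179, 149, 105 and 90.4 CPM, and 0 genes did the reverse. Some tests below used wider sets, defined by group means both without and with LPS. The first held 149 genes above 10 CPM in WT and over 4-fold lower in both mutants, the 35 included. The other held 262 genes above 10 CPM in both mutants and over 2-fold higher than in WT (0 passed a 4-fold cut). A mislabelled library is argued against. Over the 14720 tested genes outside these sets, 0 of 18 libraries were closest to a library of another line. The lowest r was 0.986 with the closest of the same line, and the highest 0.961 with another. Low depth is argued against too, since the least abundant of the 35 would have given 316 reads in the shallowest mutant library. This follows from the cut of 10 CPM by which the genes were chosen and is not a separate test. Lost segments that span several of the 35 genes are argued against for 33 of them, whose neighbouring expressed genes were not among the 35. The other 2, Msantd3 and Tmeff1, are neighbours (5.7%, against 0.7% on average and 11.4% at most in 1000 random sets). Neighbours that were lower but missed a cut for the 35 were not counted, and losses within single genes were not tested. A mixture of cells in WT may contribute, since the medians of the 149 lower and the 262 higher genes deviated oppositely over the 6 WT libraries. Pearson r was −0.95 (exact permutation p = 0.0042), and −0.81 without the 2 farthest libraries. Spearman rho was −1 (exact permutation p = 0.0028), and no other such relation was computed. But these p take the 6 libraries as independent, which libraries from 3 batches are not, and any shared axis of cell state would give the same. The labels name no more than 1 line per genotype, so effects of the targeted genes and unrelated differences between the lines cannot be told apart.

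In a second pattern, inflammatory genes had larger LPS fold changes in both mutants than in WT. The WT replicate 2 cultures as the cause are argued against as the whole cause, because without both of their libraries the median response difference of the 27 list members with counts kept 93.1% of its size in both mutants (1.85 and 1.72 in DKO, 1.08 and 1.01 in Acox1KO cells), and 10 of 12 and 10 of 11 called members were still called. A weaker stimulus in the WT cultures stays open, since the response of the 35 interferon-stimulated genes differed from WT by a median of 0.97 (quartiles 0.64 and 1.77) in DKO cells (0.95 without 1 member at 0 counts) and −0.17 (−0.64 and 0.29) in Acox1KO cells, where these genes were already higher without LPS (median 1.23) and stayed higher with it (1.06). The 12 called inflammatory genes in DKO and 11 in Acox1KO cells had median response differences of 2.90 and 3.78 on the log2 scale (2.90 and 3.31 with genes at 0 counts at their bound). Without LPS 7 and 8 of them were called lower than in WT, and the medians over all 12 and 11 were −2.29 and −3.03. With LPS 9 and 8 lay above WT by sign alone, without a test, and the medians over all 12 and 11 were 1.01 and 1.09. A median of 87.3% (quartiles 23.3% and 99.3%; 84.1% at the bound) and 74.4% (33.4% and 103.8%) of the differences thus lay in the untreated cultures, which locates the difference in genes chosen for it and does not explain it. Over all 31 members the median difference from WT on the log2 scale was −0.99 and −0.87 without LPS and 1.05 and 0.88 with it. The untreated list was lower than in WT against no change in both mutants (fry adjusted p = 0.0181 and 0.000654), and against other genes in Acox1KO cells (camera adjusted p = 0.0309; 0.69 with an estimated correlation) but not in DKO cells (0.296).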

How the results depend on the processing

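Both WT replicate 2 libraries left out together, and the replicate block for the overlap of the mutants, were chosen after the results were seen. The calls of the targeted genes were the same with RLE size factors. Counts of called genes stayed within 1.5 times under settings not given here. Against a 1.5-fold change, a stricter question by construction, they were 3499, 3147 and 1731 for DKO and Acox1KO against WT and against each other, 557, 1317 and 1775 for LPS in WT, DKO and Acox1KO cells, and 107 and 249 for the response differences of DKO and Acox1KO. With only the compared groups LPS in WT gave 516 and the response differences 307 and 508, and DKO and Acox1KO against WT gave 6989 and 6218. The same setting gave more calls for LPS in DKO (5538), LPS in Acox1KO (5191) and between the mutants (6024). Median residual SD on the log2 scale was 0.232 and 0.219 in WT without and with LPS. It was 0.131 to 0.154 in the mutant groups, and the main fit shares 1 estimate of the spread. The cause of these moves was not tested. The replicate block gave 2646 for LPS in WT and 1179 and 1532 for the differences, and the nested replicate block 3528, 2114 and 2349, and 6576 for LPS in DKO; the cause was not tested. For the DKO difference DESeq2 gave 877, and leaving out both WT replicate 2 libraries 818; the cause was not tested. The overlap of both mutants fell to 1877 genes at 2-fold and was 5961 with the replicate block. With an estimated correlation 20 of the 65 list calls passed. The replicate block turned lists far from the threshold, with adjusted p of 0.951 for mitochondrially encoded genes between the mutants, 0.972 for lysosomes with LPS in WT, and 0.899 and 0.983 for peroxisomal β-oxidation and histones in the Acox1KO difference; it ended 3 list calls and added 3. Leaving out single libraries gave 7095 to 7991 and 6711 to 7824 calls for DKO and Acox1KO against WT, 4245 to 4594 between them, 1213 to 2253, 3011 to 3693 and 3794 to 4530 for LPS in WT, DKO and Acox1KO, and 278 to 873 and 537 to 929 for the differences. The targeted genes changed sign only where they were uncalled and near 0. The Abcd1 response difference in DKO cells became 0 with RLE size factors and with DESeq2, −0.04 with total count only, −0.05 with no filter and −0.01 with limma-voom, and −0.10 to 0.13 over left-out libraries. That of Acox1 in Acox1KO cells became −0.01 with total count only and −0.02 with no filter, and −0.12 to 0.29 over left-out libraries. Over left-out libraries Abcd1 in DKO against WT spanned −0.22 to 0.01, Acox1 between the mutants −0.19 to 0.05 and the Acox1 difference in DKO cells −0.05 to 0.35; the cause was not tested. Of 6509 values of named genes under the other settings 6201 kept direction and side of the threshold, 285 lost the call, 16 gained one and 7 changed sign, and of 4524 with a library left out 4296, 210, 2 and 16 did. In simulated counts of this depth, drawn with the same spread in all groups, 1.5-fold changes of the DKO response difference were recovered in 13.4% of cases.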
